A study of Homo sapiens with 3 samples.

How the data were processed

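RNA of human hair follicle epithelial stem cells was measured after 1, 2 and 5 days of transwell co-culture with dermal papilla cells, on 1 genechip array per day, per the labels. The deposited values are linear intensities, 1 per probe set and array, which can fall below 0, so some background was subtracted before deposit. The software, the background method and the scaling target are not given in the sources used here. From the values themselves, the mean after trimming 2% at each end was 1501, 1501 and 1502, so the arrays appear to have been scaled to 1 trimmed mean. Such a scaling cannot show a change in the total amount of RNA. Medians were 397.4, 389.6 and 414.8, and maxima 85983, 102961 and 120403. The values are levels, not ratios against day 0, so the counts against day 0 and the counts over all 3 days that had been planned for ratios were not made. The comparisons are day 2 minus day 1, day 5 minus day 1 and day 5 minus day 2. Whether the arrays came from 1 or several donors or cultures is not given in the sources used here.

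Of 12625 probe sets, 10961 carried 1 gene symbol in the platform annotation, 545 carried several and 1119 were not listed there, 49 of which are control probe sets. Of all 67 control probe sets, the other 18 carried a symbol. Control probe sets, genes of the Y chromosome and XIST were left out, which left 10927 probe sets for 8210 genes. Gene symbols were brought up to date through gene identifiers in a RefSeq table (assembly GRCh38.p14), where 10949 probe sets matched and no symbol changed. Values below the 5th percentile of positive values (33.3) were set to it before log2. A gene's value was the median of log2 over its probe sets, and 1928 genes had at least 2. The level printed for a gene is the antilog of that value. Symbols are those of the annotation, and probe sets of 1 gene that disagree are named where they matter.

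With 1 array per day no test is possible, so genes were counted by size, at least 2-fold (log2 difference of 1). The median of each of 27 gene lists was set against 10000 random lists of the same size, matched on mean log2 level in 20 bins (seed 1), and given as a percentile. This describes these arrays and tests no condition. The lists, the rule for named genes and the first set of alternatives below were fixed before the data were examined. The rule took, for each comparison, the 12 highest and 12 lowest log2 differences among genes above the array median on at least 1 of the 2 days, then the 2 highest and 2 lowest members of each list, and a set of keratin, signalling and control genes. Genes at the floor on a day (45, 92 and 68 for the 3 comparisons) were not ranked, a step that the rule did not hold and that was added after the values were seen.

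A noise limit was added after the values were seen: per array, the 90th percentile of the sizes of the negative values (712.1, 695.7 and 1001). None of 19 non-human control probe sets, which nothing in the sample should bind, exceeded it on any array, and their highest values were 484.2, 687.5 and 955.7. A gene counted as above the limit on a day when its level, the median over its probe sets, was above it, even if single probe sets were not. It counted as below when all its probe sets were, and other genes counted as mixed. Where a gene was above the limit on 1 of the 2 days, the fold is given as a bound, "at least", from the bright level over the higher of the dim array's limit and the gene's own level there. List members called measured are those above the limit on at least 1 of the 2 days and not mixed, and counts of members past 2-fold include bounds. A second ranking, with values under the highest of the 3 limits raised to it and 25 genes taken from each end, was also chosen after the values were seen.

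The steps were tested on simulated data, with 2 arrays drawn from the day 1 levels with multiplicative and additive noise and 200 genes changed, for the comparison of day 5 with day 1 over 8210 genes. All 100 genes changed 4-fold or more passed 2-fold, and 21 of 50 genes changed exactly 2-fold did. Of 2286 unchanged genes at more than 2 noise limits, 59 passed 2-fold (2.58%) with the spread between probe sets of this comparison, but over all levels 2344 of 7985 unchanged genes did. The simulated noise was added to day 1 values that already carry noise, so the share over all levels is too high. The other comparisons were not simulated. A planted list of 25 low genes fell at percentile 0.05, and a list of unchanged genes at 92.5.

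The alternatives were: arrays centred on their medians, quantile normalization, the mean over probe sets, probe sets without a shared-sequence suffix, genes above the 40th percentile of mean level, a floor at the 20th percentile, no floor with values at or below 0 left out, thresholds of 1.5-fold and 3-fold, counts over probe sets, random lists without matching and the mean of members. Added after the data were seen were the noise limit as floor or as filter, and a stricter limit at the 95th percentile. Centring shifts a list and its random lists alike, so it cannot change a percentile. Among the alternatives counted for a list, that 1 was thus fixed in advance to give the call of the chosen setting. A value counted as moved under an alternative when it changed by more than the standard deviation between probe sets of a gene (0.32, 0.39 and 0.33 for the 3 comparisons) or, for a list, of the random medians. Analyses used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9.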

Results

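The labels describe epithelial stem cells isolated from human hair follicles and grown in a transwell with dermal papilla cells, the mesenchymal cell cluster at the base of the follicle that signals to its epithelium. A transwell keeps the 2 cell populations on either side of a porous membrane. RNA of the epithelial cells was hybridised to a 1-colour oligonucleotide array with 12625 probe sets. The data used here are 3 arrays, 1 each from day 1, day 2 and day 5 of co-culture. A day 0 sample and cells cultured without dermal papilla were not analysed here, so days in culture and days of co-culture cannot be told apart. The comparisons ask how the epithelial expression profile differed between these days. There was 1 array per day and no replicates, so each difference below has no replicate check. No p-value is given, and the number of arrays limits the precision.

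Median probe set intensities were 397.4 at day 1, 389.6 at day 2 and 414.8 at day 5, in the deposited linear units. Values at or below 0, which have no fold, made up 20.1%, 20.6% and 22.7% of probe sets. A noise limit per array was taken from the sizes of the negative values and lay at 712.1, 695.7 and 1001 on the 3 days. In all, 40.5%, 39.9% and 34.1% of probe sets exceeded it. The day 5 array thus had the highest noise limit, and its 9 bacterial and phage spike-in probe sets were 3.93-fold brighter than on day 1 (range 2.25 to 5.25), against 0.87-fold on day 2. Across probe sets above the limit on both days, log2 intensities correlated at r = 0.973 between day 1 and day 2, 0.939 between day 1 and day 5, and 0.957 between day 2 and day 5. These correlations are across probe sets, which are not independent replicates.

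SERPINA3, the acute-phase protease inhibitor alpha-1-antichymotrypsin, ranked first among genes higher at day 5 than at day 1 once low values were raised to the noise limit. It had an intensity of 6336 at day 1, 23356 at day 2 and 35555 at day 5, which is 5.61-fold higher at day 5. LCN2, a siderophore-binding antibacterial protein, went from 11077 to 32418 (2.93-fold), and the acute-phase protein gene SAA1 from 3933 to 11002 (2.80-fold). S100A8, a calcium-binding protein of inflamed epithelium, was 2.19-fold higher at 76348. TNFSF10, the death ligand TRAIL, was 3.25-fold higher, and the lysosomal protease CTSH 3.03-fold. RARRES1, named as a retinoic acid-responsive gene, and CRABP2, a cytoplasmic retinoic acid-binding protein, were 3.24-fold and 2.64-fold higher, each the median of probe sets that were all at least 2-fold higher. The mesenchymal cadherin CDH11 was 4.10-fold higher, and its probe sets had log2 differences of 1.80 and 2.27. CRAT, carnitine acetyltransferase, was 4.70-fold higher, ALDH3B2, an aldehyde dehydrogenase, 3.77-fold, PDZK1IP1 3.68-fold, ELAVL3, an RNA-binding protein best known from neurons, 3.67-fold, and ZFP36L1, which promotes mRNA decay, 2.82-fold. AP2A2 and DDAH2 were not above the noise limit on day 1 and were at least 5.76-fold and 3.90-fold higher at day 5.

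The neutrophil chemokine CXCL5 was at 4398 on day 1 and below the noise limit on day 5, at least 4.39-fold lower, first among genes lower at day 5 in the same ranking. PTGS2, the inducible cyclooxygenase, was at least 3.26-fold lower. HBEGF, a ligand of the EGF receptor, went from 4133 to 1380 (log2 difference -1.58), and FGFBP1, which releases fibroblast growth factors from the matrix, from 14531 to 4866 (2.99-fold lower). NT5E, the ectonucleotidase CD73, was 3.36-fold lower, and the nucleolar RNA helicase DDX21 3.86-fold. IL1RN, the interleukin-1 receptor antagonist, was 2.81-fold lower, but its probe sets disagreed in size, with log2 differences of -2.56 and -0.42. The membrane protease ADAM8 was at least 2.54-fold lower, EMP3 at least 2.89-fold, LY6G6C at least 3.34-fold, and the serpin SERPINB8 at least 2.43-fold. DKK1, a secreted Wnt inhibitor, was at 1067 on day 1 and 207.2 on day 5, below the limit, which bounds the difference at only 1.07-fold.

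**Figure D1:**
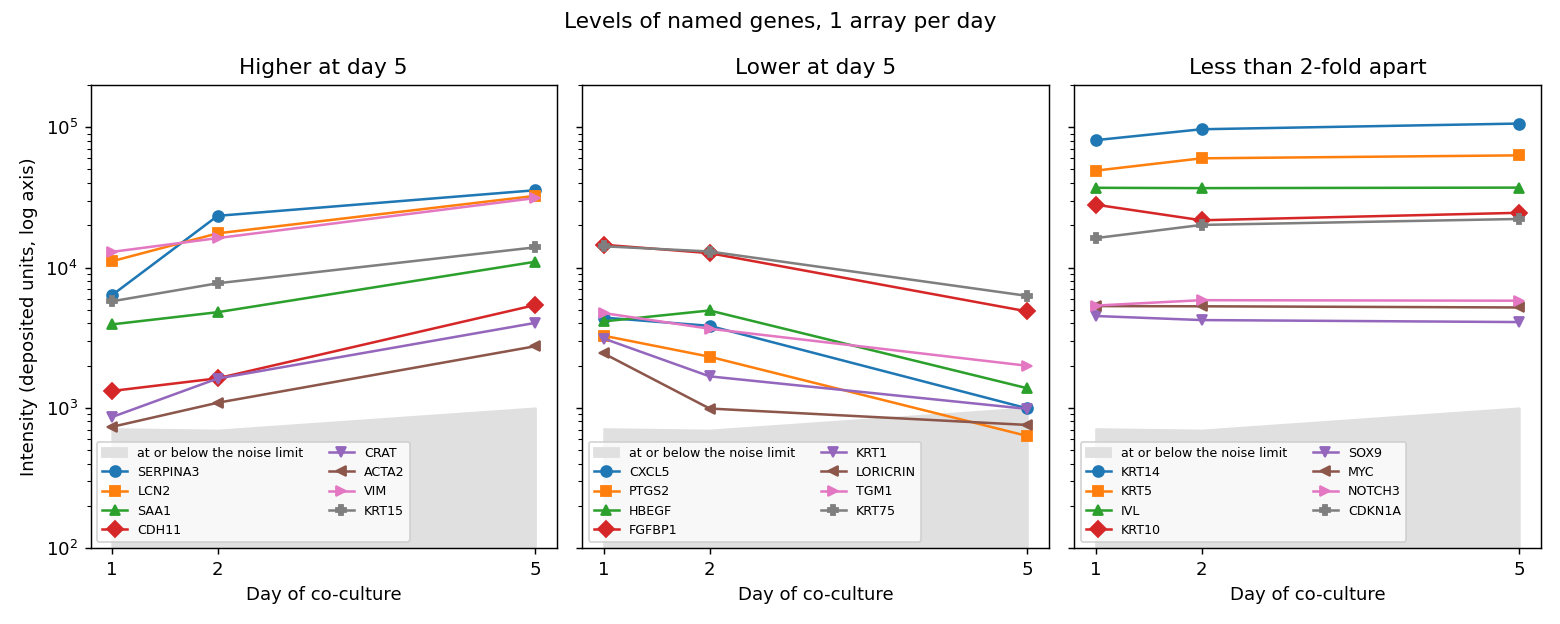
Intensity (deposited linear units, log axis) of 24 genes against day of co-culture, 1 array per day; each line joins the 3 arrays of 1 gene and the grey area lies at or below the noise limit of the array. SERPINA3 reached 35555 at day 5 from 6336 at day 1, CXCL5, PTGS2, KRT1 and LORICRIN ended below the limit, and the genes of the last panel stayed less than 2-fold apart.

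Over all 8210 genes, 707 were at least 2-fold higher and 837 at least 2-fold lower at day 5 than at day 1. Of these, 529 higher and 579 lower genes were below the limit on both days. In simulated arrays 2344 of 7985 unchanged genes passed 2-fold, a larger share than in the real arrays. The simulation added noise to day 1 values that already carry some, so it overstates noise at low levels. It is thus no reference for these counts. Since most of the counted genes were below the limit on both days, the counts are not read as a difference between days. Of 2748 genes above the limit on both days, 68 (2.47%) were at least 2-fold higher and 35 (1.27%) at least 2-fold lower. In the simulated arrays 2.58% of unchanged genes passed 2-fold, with both directions together, so many of these differences can be noise. That share is for genes at more than 2 noise limits on day 1, so it is not directly comparable. With arrays centred on their medians the split among the 2748 genes was 58 to 48, and after quantile normalization 74 to 34. The filter itself favours higher genes, since the limit is 1001 on day 5 and 712.1 on day 1. A 2-fold fall thus needs a higher starting level than a 2-fold rise. With values under the highest limit raised to it, the split over all genes was 54 to 54. Among genes above the limit on at least 1 of the 2 days it was 125 to 186. The rule fixed before the data were examined named 24 genes by size of log2 difference, from HK3 (5.14) to UPK3A (-4.31), and none of them was above the limit on both days. The genes named in the preceding paragraphs therefore come from a ranking with values under the highest noise limit raised to it, chosen after the values were seen, or from the fixed gene lists. Within genes with several measured probe sets, the log2 difference had a standard deviation of 0.39 between probe sets.

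The basal keratins KRT14 and KRT5 had intensities of 80817 and 49001 at day 1 and of 106127 and 62989 at day 5. Of 10 measured members of the basal keratinocyte and hemidesmosome list, none differed 2-fold between day 1 and day 5, and the list median of -0.02 lay at percentile 37.4 of random lists. In the bulge and stem cell list the median was 0.03 (percentile 81.0), and 1 of 7 measured members was at least 2-fold higher. That member was KRT15, the keratin commonly used to mark bulge stem cells, with 5743 at day 1, 7724 at day 2 and 13938 at day 5 (2.43-fold higher). GAS1, a growth-arrest membrane protein, had 1 of 2 probe sets above the limit at day 5 and none at day 1. SOX9, a transcription factor of follicle stem cells, was at 4516 and 4088, the activin antagonist FST at 9038 and 5634 and the integrin chain ITGA6 at 6553 and 4863. In the epidermal differentiation list, KRT1, the suprabasal keratin, was at least 3.12-fold lower at day 5, LORICRIN, the main cornified envelope protein, at least 2.44-fold lower and TGM1, the transglutaminase that cross-links the envelope, 2.37-fold lower. Involucrin (IVL, 36995 and 37109) and KRT10 (28059 and 24547) stayed within 2-fold, and S100A7 and S100A9 had log2 differences of 0.72 and 0.73. Of 19 measured members, 1 was at least 2-fold higher and 3 at least 2-fold lower, with a list median of 0.01 (percentile 34.0). That median depended on the scaling and the summary: it was -0.25 after quantile normalization, and the mean of members was -0.38 (percentile 0.54), both below the central 95%.

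Among the stress and outer root sheath keratins, KRT75, the companion layer keratin, went from 14180 at day 1 to 6279 at day 5, 2.26-fold lower, while KRT16 had a log2 difference of 0.62. The list median was 0.00 (percentile 51.8), with 1 of 8 measured members at least 2-fold lower. KRT6A and KRT17 had no probe set with 1 symbol. Hair shaft and inner root sheath genes were mostly below the limit, with 4 of 13 matched members measured. KRT31, a hair cortex keratin, was at 2630 and 2519, KRT33A at 2198 and 2206, and KRT85 stayed below the limit on all 3 days. The list median was 0 (percentile 56.5). The median of the hair follicle transcription factor list was 0 as well (percentile 52.2), and MSX2 and LEF1 were below the limit on each day.

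Genes of mitosis had low levels, and their list median depended on how low values were treated. The G2 and M phase list had a median log2 difference of -1.10, below each of the 10000 random lists, but 6 of its 28 matched members counted as measured. The median was -0.36 (percentile 10.3) among genes above the 40th percentile of mean level, -0.07 (percentile 5.40) with a floor at the 20th percentile and -0.35 (percentile 3.33) without values at or below 0. All 3 lie inside the central 95%, while the list lay outside in 6 of 10 alternatives. In this and the other tallies 1 of the 10, centring on array medians, cannot change a percentile. PTTG1, the securin gene, was at 1563 on day 1 and below the limit at day 5 (at least 1.56-fold lower), and TPX2, a spindle factor, was at least 1.20-fold lower. The kinase AURKB went from 938.4 to 319.9 and CDC20 from 915.5 to 426.3, both below the day 5 limit, while PLK1 was at 985.5 and 1443 and CKS2 at 2766 and 2167. MKI67 was below the limit on each day. No measured member passed 2-fold by its bound, and with values under the highest noise limit raised to it the list median was 0. The G1 and S phase list had a median of -0.16 (percentile 14.2) and the growth arrest list one of 0.07 (percentile 55.7). CDKN1A, the p21 inhibitor of cyclin-dependent kinases, was at 16201 and 22189.

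Signalling lists other than that of the growth factors stayed inside the central 95% of random lists between day 1 and day 5. The Wnt list had a median of 0.11 (percentile 86.2). CTNNB1, beta-catenin, had a log2 difference of 0.71 (7455 to 12225), and FZD2, a Wnt receptor, had 1 of 2 probe sets above the limit at day 5 and none at day 1, with log2 differences of 1.47 and 4.70. The BMP and TGF-beta list had a median of 0 (percentile 52.4), with TGFBI at 0.72 and ID1 at 0.67, while BMP2 and BMP4 were below the limit on each day. The Notch list had a median of 0.19 (percentile 93.7), with JAG1 at 0.40 and HES1 at -0.64, and NOTCH1 had no probe set with 1 symbol. The Hedgehog list had a median of -0.17 (percentile 7.93) and no measured member. The list of EGF, FGF and IGF ligands and receptors had a median of -0.31 (percentile 0.54), and lay outside the central 95% in 5 of 10 alternatives. It was inside with a floor at the 20th percentile (0, percentile 52.4) and with values raised to the highest noise limit. It was also inside with the mean over probe sets (percentile 3.96), unique probe sets (percentile 4.11) and the mean of members (percentile 2.78). Of its 9 measured members, 2 were at least 2-fold lower, HBEGF and the binding protein IGFBP2 (2.19-fold lower). EGFR itself was at 1376 and 1096.

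Of the response lists, matrix proteases and inhibitors had a median of -0.40 (percentile 0.20; outside in 9 of 10 alternatives), with none of 9 measured members past 2-fold; the urokinase receptor PLAUR had a log2 difference of -0.67. Inflammatory cytokines and NF-kappa-B targets had a median of -0.29 (percentile 5.08). PTGS2 and IL1RN were the 2 of 12 measured members at least 2-fold lower, IL1B was at -0.71 and CCL20 at -0.80, and NFKBIA, the inhibitor of NF-kappa-B, at 0.68. Hypoxia and glycolysis genes had a median of 0.25 (percentile 96.8), and SLC2A1, the glucose transporter GLUT1, was 2.34-fold higher at day 5. The interferon list had a median of 0 (percentile 48.8), with 1 of 21 members measured. The median was -0.18 for cholesterol and fatty acid synthesis (percentile 14.4). It was 0.16 for immediate early and heat shock genes (percentile 86.2) and -0.03 for metallothioneins (percentile 22.6). EGR1, an immediate early transcription factor, was at least 1.45-fold higher.

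Of the lists of markers of other cell types, 1 lay outside the central 95% of random lists, and the others had few measured members. The dermal papilla and fibroblast list had a median log2 difference of 1.07 between day 1 and day 5, above each of the 10000 random lists and outside the central 95% in 9 of 10 alternatives. Of its 20 matched members 5 were measured, with a median of 0.86, and with values under the highest noise limit raised to it the list median was 0. VIM, vimentin, went from 12919 to 31285 (2.42-fold higher) and ACTA2, smooth muscle actin, from 731.9 to 2751 (3.76-fold higher). FN1, fibronectin, had a log2 difference of 0.86, TAGLN one of 0.68 and SPARC one of 0.25. Of the fibrillar collagens, COL1A1 had 1 of 2 probe sets above the limit on each day, COL1A2 had 1 of 4 above it at day 5 and none before, and COL3A1 was below it on all 3 days, as were LUM and THY1. Cultured keratinocytes also express vimentin, fibronectin and actin-binding genes of this list. The melanocyte list (median 0.00, percentile 30.6, 0 of 8 members measured) and the endothelial list (0, percentile 49.1, 1 of 8 measured) stayed inside the random range. So did the leukocyte list (0.20, percentile 83.0, 2 of 11 measured), in which CD14, a co-receptor for bacterial lipopolysaccharide, was at least 2.32-fold higher. With so few members measured, these lists could not show whether such markers moved. Cytoplasmic ribosomal protein genes had a median of 0.25 (percentile 87.1) and housekeeping genes one of -0.03 (percentile 29.2). ACTB was at 40816 and 39941. The 2 probe sets of GAPDH disagreed, with log2 differences of -1.22 and 0.61. Control probe sets, left out of the gene values, also cover the 3' and 5' ends of both transcripts. From day 1 to day 5 those of GAPDH went from 58964 to 81469 (3') and from 63584 to 83263 (5'). Those of ACTB went from 56864 to 58610 (3') and from 60435 to 84998 (5').

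**Figure D2:**
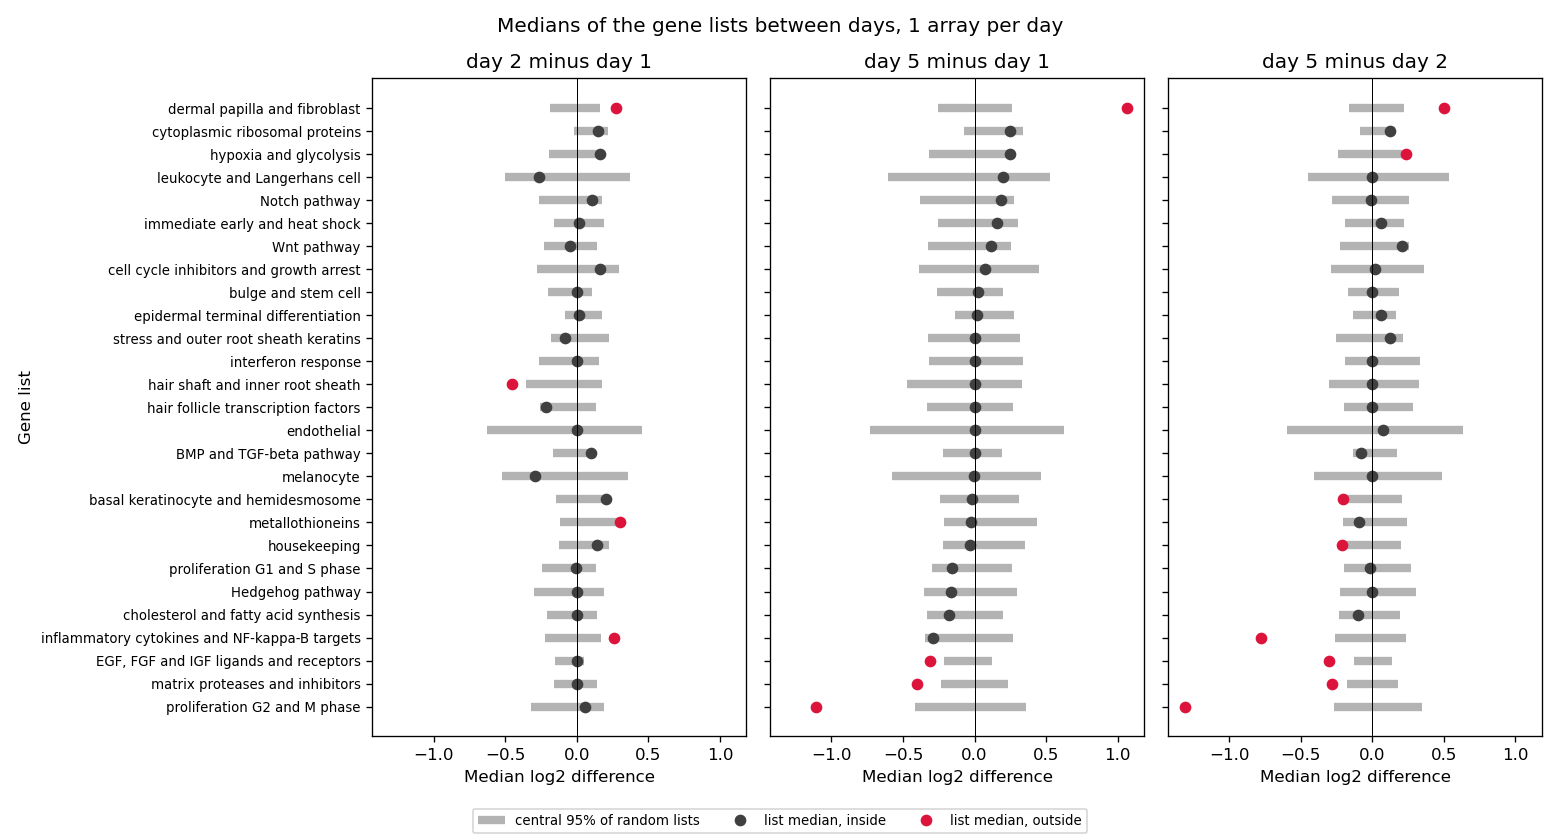
Median log2 difference of each of 27 gene lists (points) for the 3 comparisons between days (panels), with the central 95% of 10000 random lists of the same size matched on level (grey bars). Red points lie outside the bars. In day 5 minus day 1 the dermal papilla and fibroblast list lies at 1.07 and the G2 and M phase list at -1.10.

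Between day 1 and day 2 fewer measured genes differed. SERPINA3 was 3.69-fold higher at day 2, MAP2K3, a stress kinase, 2.41-fold, ALDH3B2 2.17-fold and ZFP36L1 2.15-fold. UBE2C, an ubiquitin-conjugating enzyme of mitosis, was at 2755 on day 2 alone and below the limit on the other days, at least 3.87-fold higher than at day 1. TFAP2A, a transcription factor of epidermis, was 2.17-fold higher, with probe set values from 0.20 to 1.66. Its sign turned (log2 difference -0.54) when values at or below 0 were left out. The medians of the 2 days then rested on different probe sets, since each probe set was higher at day 2. On the other side LORICRIN was 2.47-fold lower at day 2, LY6G6C 2.38-fold, the replication helicase subunit MCM2 2.61-fold and FKBP9 2.03-fold. IGFBP3, an insulin-like growth factor binding protein, was 2.08-fold lower, with both probe sets at log2 differences near -1.05. At least 1 of the 2 was not above the limit on both days. KRT15 and VIM were at log2 differences of 0.43 and 0.33. Over all genes 465 were at least 2-fold higher and 536 at least 2-fold lower, while of 3227 genes above the limit on both days there were 12 (0.37%) in each direction. Within-gene probe sets differed by a standard deviation of 0.32. Of 18 measured probe sets past 2-fold that had other measured probe sets of the same gene, 11 had these with a median of the same sign. For day 5 minus day 1 it was 24 of 31. Of all measured probe sets 46.4% were higher at day 2 than at day 1, so a shared sign is a weak check. That median reached a log2 difference of 1/2 in the same direction for 0 of the 18, against 14 of the 31. After quantile normalization the measured genes past 2-fold were 12 higher and 5 lower.

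By gene list, inflammatory cytokines and NF-kappa-B targets were on balance higher at day 2 than at day 1, with a median of 0.26 (percentile 99.7; outside in 8 of 10 alternatives). CXCL8, the chemokine interleukin-8, had a log2 difference of 0.79 (probe sets -0.19 and 1.77) and NFKBIA one of 0.77, and no measured member passed 2-fold. The dermal papilla and fibroblast list (0.27, percentile 99.5) and the metallothioneins (0.30, percentile 97.9) also lay above the central 95%, each in 7 of 10 alternatives, the latter with MT2A, a zinc-binding protein, 1.87-fold higher. The hair shaft and inner root sheath list lay below it (-0.45, percentile 0.945), with KRT31 1.80-fold lower. That median rests on members in the noise, since 3 of 13 were measured on both days. It was 0 (percentile 51.8) with a floor at the 20th percentile, and the mean of members was -0.10 (percentile 47.7). In all, 4 of 27 lists lay outside the central 95%, as did 4 between day 1 and day 5 and 8 between day 2 and day 5, and 1, 2 and 2 with values raised to the highest noise limit. About 1.35 per comparison would do so among independent random lists.

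Between day 2 and day 5, of 2770 genes above the limit on both days, 49 (1.77%) were at least 2-fold higher and 14 (0.51%) at least 2-fold lower. Centred on array medians the split was 35 to 23. The higher limit of day 5 favours higher genes here too. With values under the highest limit raised to it, the split over all genes was 35 to 24. Among genes above the limit on at least 1 of the 2 days it was 98 to 125. CDH11 was 3.33-fold higher at day 5 than at day 2, ADAMTSL2, a secreted matrix protein, 2.83-fold, PTGS1, the constitutive cyclooxygenase, 2.35-fold, ACTA2 2.53-fold, CRAT 2.49-fold and SAA1 2.29-fold. HBEGF was 3.58-fold lower, FGFBP1 2.60-fold, FDPS, an enzyme of the mevalonate pathway, 2.15-fold, EGFR 2.14-fold and KRT75 2.07-fold. CXCL5 was at least 3.83-fold lower, UBE2C at least 2.75-fold and PTGS2 at least 2.31-fold. Over all genes 641 were at least 2-fold higher and 670 at least 2-fold lower. It shares an array with each of the other comparisons, so the 3 are not independent.

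The inflammatory list was lower at day 5 than at day 2, with a median of -0.78, below each of the 10000 random lists and outside in 10 of 10 alternatives. CXCL2, a neutrophil chemokine, was at least 2.13-fold lower and IL1B had a log2 difference of -0.96. The G2 and M phase list had a median of -1.31, also below each random list and outside in 9 of 10, with UBE2C the member past 2-fold. Of its 28 members 7 were measured, and the 2 above the limit on both days had a median of 0.12. The list median was -0.34 with a floor at the 20th percentile and 0 with values raised to the highest noise limit. The growth factor list (-0.30, percentile 0.10) and the matrix proteases (-0.28, percentile 0.28) lay below the central 95%, and the dermal papilla and fibroblast list (0.50, percentile 99.9) above it, each in 9 of 10 alternatives. Calls near the edge were less stable. The basal keratinocyte list (-0.21, percentile 2.37) was outside in 5 of 10 alternatives, and inside after quantile normalization (percentile 2.91) and for the mean of members (percentile 9.50). The housekeeping list (-0.21, percentile 1.73) and, above the range, the hypoxia and glycolysis list (0.23, percentile 98.5) were outside in 6 of 10. Of the genes past 2-fold between day 1 and day 5 and above the limit on both days, the day 2 level lay between the other days for 56 of 68 higher and 31 of 35 lower genes. Pooled over all orders of the day labels, with the true order and its reverse among them, this share was 76.5% among genes above the limit on every day. That reference contains the observed differences and is no independent chance rate.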

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

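The tests of spike-in signal and of probe set agreement reported here were chosen after the results were seen; the count after quantile normalization was planned as a test before its value was seen. The spike-in probe sets, which none of the comparisons use, were 3.93-fold brighter on day 5 than on day 1 as a geometric mean of 9 probe sets. The arrays appear to have been scaled to 1 trimmed mean, so the deposited scale could not show an array-wide change. Outside the gene table, 22 probe sets with no symbol or several were at least 2-fold higher and 8 at least 2-fold lower at day 5 than at day 1, of 453 above the noise limit on both days. Between day 1 and day 2 these numbers were 7 and 6 of 520. The limit is higher on day 5, so the filter favours higher probe sets at day 5.

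More measured genes differed 2-fold between day 1 and day 5 (68 higher, 35 lower) than between day 1 and day 2 (12 in each direction). Higher noise on the day 5 array would make probe sets of 1 gene move apart, and their standard deviation was 0.39 for day 5 minus day 1 against 0.32 for day 2 minus day 1. For day 5 minus day 2, which uses the same day 5 array, it was 0.33. The share of variance that probe sets of a gene had in common was 37.2% for day 5 minus day 1 (95% bootstrap interval over 411 genes 26.7 to 47.6) against 17.0% for day 2 minus day 1 (8.84 to 24.4), and 41.2% for day 5 minus day 2 (29.1 to 52.9). The larger spread of day 5 minus day 1 goes with noise. The common shares, and the spread of day 5 minus day 2, speak against noise as the whole cause, and its part stays open. Uneven scaling is argued against by quantile normalization, after which 108 measured genes were past 2-fold at day 5, against 17 at day 2. Handling particular to the day 5 array, such as the amount of RNA or of spike-in used, stays open. The spike-in fold of 3.93 shows that something in it differed, and with 1 array per day it cannot be told apart from a biological change over time.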

How the results depend on the processing

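Counts of genes past 2-fold depended mostly on the treatment of low values. They are given as higher and lower for day 2 minus day 1, then day 5 minus day 1, then day 5 minus day 2. The chosen setting gave 465 and 536, 707 and 837, 641 and 670. Genes above the 40th percentile of mean level gave 128 and 141, 274 and 328, 231 and 247. A floor at the 20th percentile gave 140 and 178, 356 and 378, 304 and 257. Values under the highest noise limit set to it gave 6 and 10, 54 and 54, 35 and 24. Genes above the noise limit on both days gave 12 and 12, 68 and 35, 49 and 14. Those above it on at least 1 of the 2 days gave 52 and 69, 125 and 186, 98 and 125. The stricter limit on both days gave 5 and 4, 36 and 20, 21 and 8. The noise limit settings were added after the values were seen.

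A 1.5-fold threshold gave 862 and 1060, 1269 and 1472, 1203 and 1169. A 3-fold threshold gave 229 and 254, 349 and 441, 300 and 347. Counted over probe sets the numbers were 808 and 888, 1194 and 1236, 1067 and 1014. Centring, quantile normalization, the mean over probe sets and unique probe sets kept each count within 1.5 times the chosen one. So did leaving out values at or below 0, but it turned the balance of the day 5 comparisons: 446 and 513, 725 and 626, 690 and 506.

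The number of lists outside the central 95% was 4, 4 and 8, and centring on array medians cannot change it. With values under the highest noise limit set to it, it was 1, 2 and 2. With a floor at the 20th percentile it was 2 for day 5 minus day 1, and with the mean of members it was 2 for day 2 minus day 1. In all, 642 list medians stayed the same under an alternative and 159 moved. The 642 include those set against random lists without matching, which leave a list's own median as it is.

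Of the values of named genes under an alternative, 989 stayed the same, 53 moved and 3 changed sign. Part of the 989 was fixed in advance. The filter at the 40th percentile of mean level leaves a kept gene's value as it is (126 values). Centring shifts all values of a comparison alike, by less than the cut-off for a moved value (134 values). The sign changed where values at or below 0 were left out: TFAP2A in day 2 minus day 1 (-0.54), MKI67 (0.39) and COL1A1 (-0.52) in day 5 minus day 1. In that setting the median of each day is taken over the probe sets left on that day. For TFAP2A each probe set was higher at day 2, so its turned sign came from different probe sets on the 2 days. The cause was not tested for MKI67, COL1A1 or the lists. The noise limits, 712.1, 695.7 and 1001, bound what can be seen of genes with low signal. No paired analysis was possible because each day had 1 array and no pairs. No array could be left out of a comparison for the same reason.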

Other observations

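The tests reported here used results already seen, except the percentiles of the wider defence and retinoid lists, which were written down first. Beyond the genes described above, other genes above the noise limit on both days were at least 2-fold higher at day 5 than at day 1, chosen after their values were seen. They include AKR1C3, a steroid- and prostaglandin-metabolising reductase (2.54-fold), the neutrophil chemokine CXCL6 (2.54-fold), the peptidase MME (2.45-fold), the cytokine LIF (2.23-fold), the stress cytokine GDF15 (2.16-fold), the transcription factors SOX4 (2.24-fold) and HIF1A (2.04-fold), and LOX, which cross-links collagen (2.02-fold). Lower at day 5 were the neuropeptide genes NMU (2.41-fold lower) and GAL (2.37-fold lower), the tight junction protein CLDN4 (2.29-fold lower), the phosphatase DUSP4 (2.10-fold lower) and the ribosome assembly factor NOLC1 (2.12-fold lower). CXCL5 and CXCL6, related chemokines, thus differed in opposite directions.

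The higher dermal papilla and fibroblast list at day 5 could come from dermal papilla cells carried over, although a transwell membrane separates the cells, or from the epithelial cells themselves. Of 14 members below the noise limit on day 1, collagens and lumican among them, 0 were above it on day 5 with all their probe sets, 1 (COL1A2) was with at least 1 probe set, and 7 had a log2 difference of at least 1. The 6 members with a probe set above it on day 1, vimentin and fibronectin among them, had a median log2 difference of 1.07, against 1.04 for the 14. The fibroblast genes below the limit on day 1 did not come up clearly, but levels this near the noise exclude nothing. Outside the list, the mesenchymal cadherin CDH11, chosen after its value was seen, was above the limit on both days and 4.10-fold higher at day 5. With these values, carry-over of dermal papilla cells and an epithelial change cannot be told apart.

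The lower median of the G2 and M phase list at day 5, which depended on the floor, could reflect low signal of the members. The 7 members above the noise limit on day 1 had a median log2 difference of -1.11, at percentile 0.075 of random lists of such genes, whose median was -0.26. Of the 7, 2 were above the limit on both days, so low signal is not excluded. Time in culture without the dermal papilla is open as well, since 0 arrays of cells cultured without it were analysed here. A slowing of division during co-culture is a hypothesis that these arrays leave open.

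Because SERPINA3, LCN2, SAA1 and S100A8 were higher at day 5 than at day 1, a hypothesis was that antimicrobial and acute phase genes moved together. A list of 31 such genes matched 25, with a median log2 difference of 0.58. That number rests on genes already seen. Without the 10 seen before, the other 15 had a median of 0.23, at percentile 93.8 of random lists, inside the central 95%. Of the 15, 3 were above the limit on both days. A common rise of the wider group was thus not shown, nor was one excluded. Retinoid-responsive genes were examined in the same way because of RARRES1, CRABP2 and TNFSF10. Without these, 17 genes had a median of 0, at percentile 52.9, and none of the 4 above the limit on both days was 2-fold higher. These 4 had log2 differences of 0.87 (DHRS3), 0.32 (ALDH1A3), 0.22 (BHLHE40) and -0.48 (NRIP1). Most of the 17 were not above the limit on both days, and members went both ways. The list thus cannot tell whether a general retinoid response lies behind the 3.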
